A study of Mus musculus with 4 samples.

How the data were processed

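The series holds 4 single-cell RNA libraries from mouse lung, 1 for each of 3 embryonic ages (E14.5, E16.5, E18.5) and 1 for the day of birth (P0). Per the labels, each library came from a pool of 3 to 5 animals of the Prox1-GFP genotype, and cells negative for the leukocyte antigen CD45 and positive for both the endothelial antigen CD31 and the reporter were sorted before droplet capture with a 3' end kit from 10x Genomics. The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, without normalisation. The submitters' processing notes name Cell Ranger, with no version, Seurat 2.3.4 and the mm10 genome; which filters they applied is not given in the sources used here. All 4 matrices list the same 27998 genes, but the gene list of P0 has a column, of feature type, that the other 3 lack. Whether P0 was processed with another software version is not given in the sources used here, and this bears on every ratio with P0.

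Cells were kept with at least 500 genes detected and at most 10% of UMIs from mitochondrially encoded genes, and doublets were called per library with the Scrublet method in scanpy. Scrublet called 76 of 11991 cells (0.634%), of which 3 of 2750 were in E16.5, so undetected doublets remain possible. Counts were scaled to 10000 per cell and log1p-transformed, and 2000 variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 were used on the 4 libraries together, without batch correction. Clusters were named from marker lists of 14 cell types and of valve and capillary lymphatic endothelial cells (LECs). A marker was present at 50 CPM (counts scaled to a library total of 1000000) or more in the cluster. A cluster was called LEC-like with at least 8 of the 10 LEC markers, and no other cluster had more than 6. A cluster took the class with the largest share of its markers, with at least 3 of them present. It was left unnamed where another class had more markers among the cluster's 10 leading genes, and an endothelial class was not given to a cluster in which the leukocyte genes Ptprc and Tyrobp were both present. These naming thresholds were set after the data had been seen, whereas the marker lists, gene lists, comparisons and filters were fixed before the data were examined.

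UMIs were summed over the LEC-like cells of a library and expressed as CPM. A gene entered a comparison at 50 CPM or more in at least 1 of the 2 libraries, and was counted when its ratio was at least 2 either way. Each ratio has an exact conditional 95% interval and each share of cells an exact (Clopper-Pearson) binomial 95% interval. These intervals cover counting error only. With 1 library per stage there are no replicates, cells are not replicates, and no test between stages was possible, so counts of genes at least 2-fold apart are sizes between 2 libraries. Where a library had 0 UMIs of a gene, the ratio was taken against a floor of 3 counts in that library, which corresponds to 0.317 CPM at E14.5, 0.477 at E16.5, 0.397 at E18.5 and 0.232 at P0. In the log2 ratios used to count and rank genes and for medians, any count below 3 was raised to this floor. Beside a bound of 3 counts the limit of the exact interval is given.

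For each of 25 gene lists, the median log2 ratio of members at 10 CPM or more in at least 1 of the libraries was set against 10000 random lists of the same size, drawn from 20 bins of mean expression, and members at least 1.5-fold apart were counted. A list with fewer than 3 such members was given no median. The genes named one by one were chosen by rule. For E18.5 against E14.5 they were the 12 largest and the 12 smallest ratios among genes with a UMI in at least 10% of LEC-like cells of the higher library and with E16.5 in between. For P0 against E18.5 the rule was the same without the last condition, and for both 2-day steps it was the 5 largest and the 5 smallest. Mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked genes, numbered gene models and markers of cell types other than LEC were left out of that ranking. For P0 against E18.5, 1 gene of the ranking is not reported here. Members of the lists, cell type markers and the 5 leading genes of a valve or capillary cluster could also be named.

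Dividing cells were counted after each cell had been thinned at random to 3000 UMIs, the largest of 4 preset depths that kept at least 90% of LEC-like cells in every library. LEC-like cells were also clustered again, with each gene scaled within its library and without the cell cycle lists. A valve cluster needed at least 3 valve markers 2-fold higher than in the other LEC-like cells in each library in which it had at least 20 cells. Gene positions are 1-based and come from GENCODE vM21 on GRCm38, the assembly also called mm10.

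The ratio, interval and list procedures were tested on simulated data in which 200 genes were made to differ by 1.5-fold or 3-fold. In each of the 5 comparisons, 100 of 100 genes at 3-fold and 0 of 100 genes at 1.5-fold were counted, 0 unchanged genes were counted, and between 94.3% and 95.4% of the intervals held the true ratio. The simulated data were Poisson counts drawn around a profile shared by the libraries, with changed genes taken from above the 50 CPM filter. They held no variation between libraries, pools or cells. The test therefore checks the procedures and says nothing about false calls between real libraries. Other settings, also chosen beforehand, were other scalings of the libraries, an equal weight for every cell, other filters on genes and cells, doublets kept, all cells in place of LEC-like cells, non-dividing cells, thinned cells, cells of each sex, other clustering settings and other thresholds. Added after the data had been seen were LEC-like cells without cluster 8, 2 clusters of the second clustering, and genes without pseudogenes and numbered models. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.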

Results

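Gene expression was measured in single cells of the developing mouse lung, sorted for endothelial cells that carried a green fluorescent reporter of Prox1, the transcription factor that sets lymphatic identity. There was 1 library for each of 4 stages, which were E14.5, E16.5 and E18.5 before birth and P0 on the day of birth. They held 3815, 2804, 2268 and 3496 cell barcodes, with 62246794, 32195724, 21174661 and 23454639 UMIs in all. Filtering left 3762, 2747, 2191 and 3215 cells, 11915 together.

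The first question was which cells the sort had collected. LEC-like cells made up 585 of the cells kept at E14.5 (15.6%, 95% interval 14.4 to 16.7), 526 at E16.5 (19.1%, 17.7 to 20.7), 679 at E18.5 (31.0%, 29.1 to 33.0) and 1687 at P0 (52.5%, 50.7 to 54.2). Over the 4 libraries the 3477 LEC-like cells had 551 CPM of Prox1, 349 CPM of the VEGF-C receptor gene Flt4 and 23524 CPM of Ccl21a, a chemokine that guides dendritic cells and T cells into lymphatics. In blood endothelial-like cells the same genes had 28.9, 34.1 and 313 CPM. Lyve1, a hyaluronan receptor of lymphatic capillaries, was less specific, with 935 CPM in LEC-like and 434 CPM in blood endothelial-like cells. UMIs of Ccl21a may be shared with its near-identical copies, so its level is uncertain.

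Prox1 UMIs were found after thinning in 58.6%, 70.9%, 75.9% and 82.6% of LEC-like cells from E14.5 to P0. In blood endothelial-like cells, which were sorted for the same reporter, the shares were 6.73%, 7.21%, 9.49% and 8.25%. At full depth the shares were 96.4%, 95.1%, 97.2% and 95.7% of LEC-like cells and 23.3%, 22.6%, 21.6% and 16.9% of blood endothelial-like cells. Median depths before thinning were 15504, 10682, 9699 and 7086 UMIs per LEC-like cell and 18044, 9628, 6805 and 5479 UMIs per blood endothelial-like cell. Blood endothelial-like cells were 34.7%, 49.0%, 53.4% and 44.8% of the cells kept, and cells of unnamed clusters 35.7%, 23.01%, 5.43% and 1.34%. Cluster 2, led by mitosis genes, held 26.1%, 15.3%, 3.56% and 1.99% of the cells kept, and cluster 4, with Nrg1 among its leading genes, 7.52%, 28.7%, 1.83% and 0.280%. Cluster 7, with the arterial genes Gja5 and Cxcl12, held 1.14%, 4.37%, 4.84% and 1.74%. Clusters 13, 14 and 15 were nearly absent before E18.5: cluster 13, with the capillary gene Gpihbp1, held 0.027%, 0.291%, 14.7% and 16.6%, cluster 14 held 0%, 0.328%, 23.6% and 20.6%, and cluster 15, with Car4, held 0%, 0%, 4.79% and 3.61%. Clusters 3 and 9, led by haemoglobin genes and left unnamed, held 33.3%, 1.57%, 0.411% and 0.156% and 1.62%, 18.6%, 1.32% and 0.560%. In both, the class with the largest share of markers present was blood endothelial, with 6 of 10 and 8 of 10. At E14.5 a Pecam1 UMI was found after thinning in 71.9% of unnamed and 70.0% of blood endothelial-like cells. The share of blood endothelial-like cells thus depends on the naming rule. These shares depend on the sort gate as well as on the tissue. Because the libraries were clustered without batch correction, the near absence of a cluster from a stage cannot be separated from a difference between libraries.

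**Figure D1:**
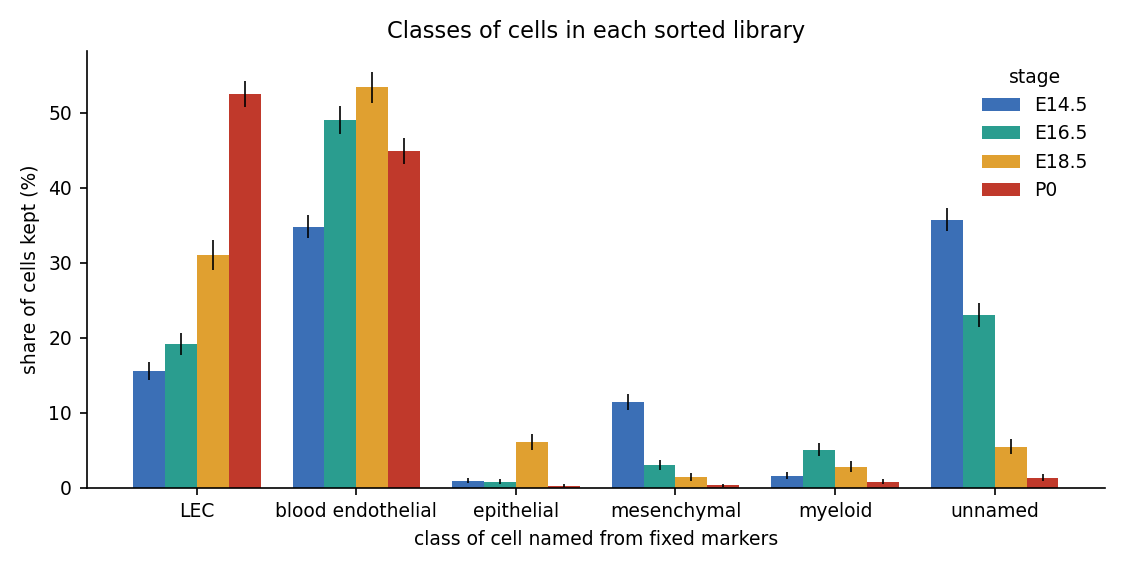
Share of the cells kept (%, vertical axis) in each class named from markers (horizontal axis), for the 4 libraries, with exact binomial 95% intervals as error bars. LEC-like cells were 15.6% of the E14.5 library and 52.5% of the P0 library.

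Which genes set LEC-like cells of late gestation apart from those of mid-gestation was addressed by E18.5 against E14.5, with 679 and 585 cells. The secreted fibrinogen-like protein gene Fgl2 was 28.8-fold higher at E18.5 (95% interval 25.2 to 33.1), with 23.8 CPM at E14.5 and 685 CPM at E18.5. Lrg1, which encodes a secreted modulator of TGF-beta signalling in vessels, was 65.3-fold higher (42.1 to 107), and the water channel gene Aqp1 was 28.2-fold higher (23.8 to 33.7). Mdk, a heparin-binding growth factor gene typical of embryonic tissue, was 8.79-fold lower at E18.5 (7.13 to 10.9). Hmga2, which encodes a chromatin protein and is a target of let-7 microRNAs, was 22.1-fold lower (11.5 to 49.0).

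In all, 3097 genes were compared, of which 248 were at least 2-fold higher and 124 at least 2-fold lower at E18.5. Among the highest ratios were also Clca3a1 at 35.4-fold (20.8 to 65.3), the microtubule regulator Stmn2 at 32.5-fold (22.99 to 47.6), the long noncoding RNA Neat1 at 23.2-fold (16.5 to 33.6), the iron-siderophore-binding lipocalin Lcn2 at 20.5-fold (15.5 to 27.6), the Notch pathway ubiquitin ligase Dtx1 at 16.04-fold (11.9 to 22.0), the matrix protein gene Fbln2 at 14.3-fold (11.2 to 18.6) and the sulfotransferase gene Sult1a1 at 13.6-fold (10.8 to 17.4). With LEC-like cells clustered again, 1 cluster held 14 of 585 cells at E14.5 and 147 of 679 at E18.5. Clca3a1 had 10.7 and 174 CPM inside it at these stages, and 1.29 and 23.3 CPM outside. Stmn2 had 32.1 and 362 CPM inside, and 2.91 and 54.0 CPM outside. Both genes were thus higher at E18.5 inside and outside, but their ratios over all LEC-like cells also carry the larger share of this cluster. Lyz1, with 0 UMIs at E14.5, was at least 257.5-fold higher against the floor of 3 counts, with an exact lower limit of 208.8, and Ager was 25.7-fold higher (16.6 to 42.0). Both were among the genes that led the epithelial-like cluster 11. At E18.5 Lyz1 had 81.6 CPM in LEC-like cells and 79.9, 76.8 and 80.8 CPM in clusters 10, 13 and 14. Ager had 57.1 CPM in LEC-like cells and 48.2, 52.6 and 51.2 CPM in those clusters. Their levels at E18.5 were therefore not particular to LEC-like cells. Sftpc, the surfactant gene of that cluster, had 1.37, 43.1, 721 and 20.5 CPM in LEC-like cells from E14.5 to P0, and the haemoglobin gene Hba-a1 had 2.96, 11.9, 23.6 and 12.8 CPM. The lower genes included the signalling protein gene Basp1, 6.71-fold lower at E18.5 (5.67 to 7.998), the prostaglandin-degrading enzyme gene Hpgd at 4.93-fold (4.05 to 6.04), the fetal RNA-binding protein gene Igf2bp1 at 4.59-fold (3.64 to 5.84), Phgdh of serine synthesis at 3.75-fold (3.17 to 4.45), the DNA repair enzyme gene Apex1 at 3.39-fold (2.97 to 3.87) and Uhrf1, which maintains DNA methylation, at 3.27-fold (2.69 to 4.01). Nme4, Nnat, Ppa1, Fbln1 and Bex2 were between 3.61-fold and 3.98-fold lower.

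Lymphatic identity genes were higher at E18.5 in 11 of 12 measured members, with a median log2 ratio of 1.01 at percentile 100 of the random lists. Lyve1 was 7.78-fold higher (7.31 to 8.29), Fxyd6 3.25-fold (3.06 to 3.45), Reln 3.14-fold (2.95 to 3.33) and Prox1 2.12-fold (2.02 to 2.22), while Nrp2, a co-receptor for VEGF-C, was within 1.5-fold. The list was also higher in arterial blood endothelial cluster 7 (8 of 11 higher, median 1.09), and in cells other than LEC-like ones Lyve1 had 133 CPM at E14.5 and 554 CPM at E18.5. Of 8 valve genes 6 were higher (median 1.45), among them Cldn11 at 12.9-fold (10.3 to 16.4), the gap junction gene Gja4 at 12.4-fold (10.8 to 14.3) and Foxc2, a transcription factor needed for lymphatic valves, at 4.22-fold (3.33 to 5.40). Part of the Cldn11 ratio lay in a valve cluster, described below, of 0 cells at E14.5 and 32 at E18.5. Cldn11 had 8.66 CPM in LEC-like cells at E14.5. At E18.5 it had 1234 CPM in that cluster and 63.0 CPM in the other LEC-like cells. All 8 measured flow response genes were higher (median 1.75), including Klf4 at 7.45-fold (6.30 to 8.85), Thbd at 4.55-fold (3.66 to 5.69) and Klf2 at 3.02-fold (2.79 to 3.27). Foxc2 and Gata2 are members of both the valve and the flow response list, so the results of these lists are not independent.

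Genes of immune function were higher at E18.5 as well, and so were some transcripts of leukocytes in LEC-like cells, with 0.317 and 24.8 CPM of the granulocyte gene S100a8, 2.64 and 43.8 CPM of Lyz2 and 3.48 and 16.2 CPM of Tyrobp at E14.5 and E18.5. All 6 measured interferon response genes were higher, with a median log2 ratio of 3.25, and among them Isg15 was 29.5-fold higher (17.0 to 56.1), Ifi27 20.97-fold (13.04 to 35.9) and the antiviral gene Ifitm3 6.88-fold (6.43 to 7.37). All 7 genes of MHC class I antigen presentation were higher (median 2.20), with H2-T23 at 9.25-fold (6.63 to 13.2) and H2-D1 at 4.59-fold (4.19 to 5.04), and so were all 7 leukocyte traffic genes (median 1.57), with the chemokine Ccl2 at 7.46-fold (4.62 to 12.7) and the adhesion molecule Icam1 at 4.55-fold (3.35 to 6.27). Basement membrane and matrix genes were higher in 8 of 14 (median 0.62), with elastin, Eln, at 9.68-fold (8.68 to 10.8) and the collagen gene Col4a1 at 2.05-fold (1.92 to 2.18). Of 11 fatty acid handling genes 7 were higher and 1 was lower (median 1.08). Fabp4 was 3.10-fold higher (2.94 to 3.27), and its paralog Fabp5 was the 1 that was lower, by 2.60-fold (2.46 to 2.75). Glucocorticoid response genes were higher in 6 of 7 (median 1.77), among them Sgk1 at 3.42-fold (3.03 to 3.87), and immediate-early genes, many of which respond to tissue dissociation, in 10 of 12 (median 1.63), among them Fos at 7.32-fold (6.19 to 8.71).

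Genes of cell division were lower at E18.5. DNA replication genes were lower in 16 of 17 (median −1.22), with the helicase subunit Mcm5 2.74-fold lower (2.35 to 3.20), and all 16 genes of G2 and mitosis were lower (median −1.02), with Ube2c 2.48-fold (2.33 to 2.63) and Cdk1 2.44-fold lower (2.21 to 2.69). Fetal RNA-binding and let-7 target genes were lower in 3 of 4 (median −2.50). Oxidative phosphorylation genes were lower in 3 of 16 (median −0.41, percentile 1.47), with Cycs 1.82-fold lower (1.73 to 1.93). Glycolysis and hypoxia genes went both ways, with 4 of 16 higher and 5 lower (median −0.12, percentile 29.5). Adm was 14.1-fold higher (8.33 to 25.8) and Ldha 1.98-fold lower (1.89 to 2.07).

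Of the signalling lists, angiopoietin and TIE genes were higher in 4 of 5 (median 1.02), with Tie1 2.03-fold higher (1.91 to 2.17), and BMP and TGF-beta genes in 5 of 9 (median 0.62), with Id2 4.25-fold higher (3.43 to 5.31). Endothelial junction genes were higher in 3 of 7 (median 0.57), with the tight junction gene Cldn5 1.80-fold higher (1.75 to 1.84). The VEGF pathway (3 of 5 higher, median 0.70), Notch pathway (3 of 7, median 0.54) and Wnt and beta-catenin (1 of 6, median 0.31) lists lay inside the middle 95% of random lists, as did imprinted growth genes (4 of 10 higher, 1 lower, median 0.34), ribosomal proteins (2 of 18 higher, 0 lower, median −0.26), mitochondrially encoded genes (1 of 10 higher, median 0.15) and sex-linked genes (0 of 3, median 0.28). Among the imprinted genes H19 was 2.46-fold higher (2.42 to 2.501) and Mest 2.21-fold lower (2.15 to 2.28). With median-of-ratios scaling the split was 210 higher and 171 lower. Of the 248 higher genes, 33 were pseudogenes or numbered gene models, whose counts can include UMIs of near-identical genes, out of 45 such genes compared.

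**Figure D2:**
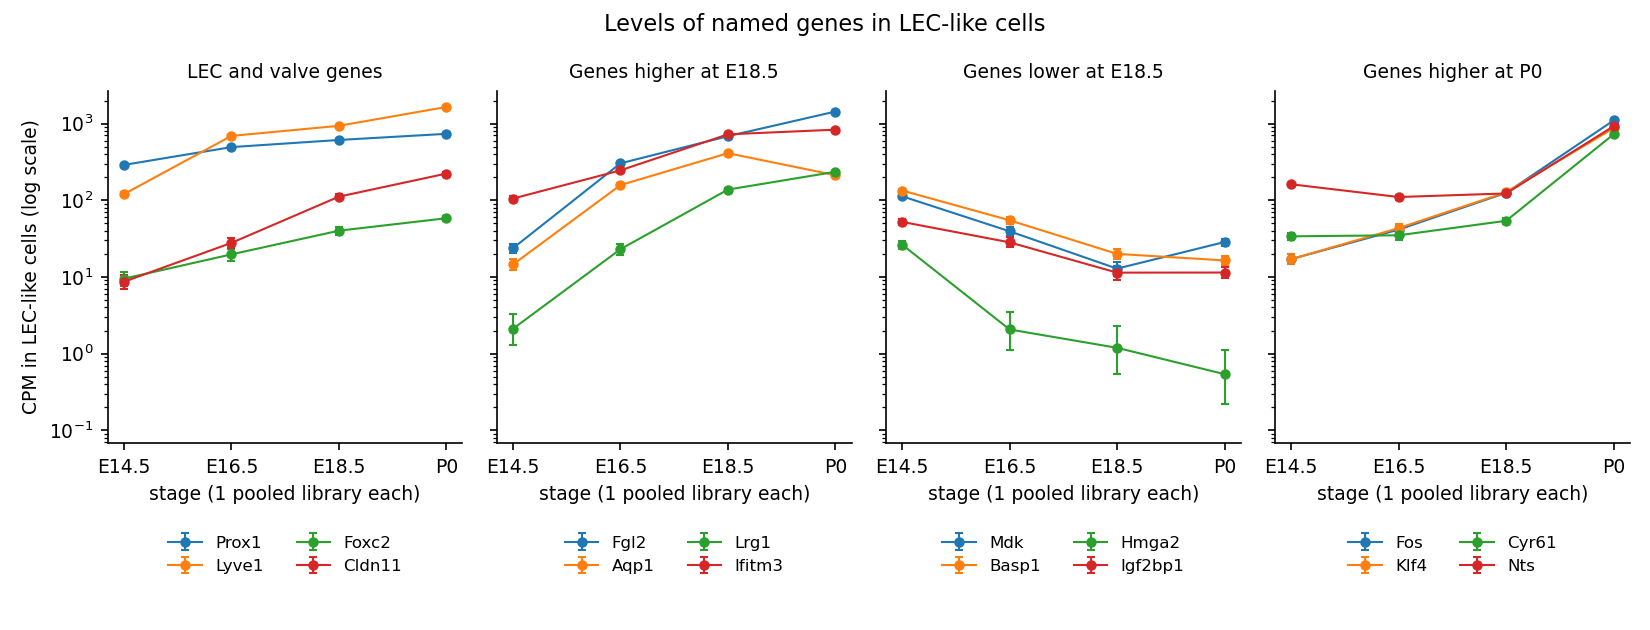
CPM in LEC-like cells (vertical axis, log scale) of 16 named genes at the 4 stages (horizontal axis, 1 pooled library each), with exact Poisson 95% intervals for counting error as error bars. Fgl2 had 23.8 CPM at E14.5 and 685 CPM at E18.5, and Fos had 125 CPM at E18.5 and 1101 CPM at P0.

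What set apart the earlier step, E16.5 against E14.5, was compared with 526 and 585 cells. Fgl2 was 12.8-fold higher at E16.5 (11.1 to 14.7), Aqp1 10.8-fold (9.07 to 13.1), Fbln2 10.7-fold (8.27 to 13.97), Sult1a1 8.25-fold (6.48 to 10.6) and Eln 6.47-fold (5.77 to 7.27). Phgdh was 3.28-fold lower (2.76 to 3.90), Mdk 2.86-fold (2.49 to 3.30), Basp1 2.45-fold (2.17 to 2.76), Bex2 2.35-fold (1.99 to 2.80) and Nme4 2.18-fold lower (1.88 to 2.54). Hmga2 had 26.4 CPM at E14.5 and 2.07 CPM at E16.5, a 12.8-fold lower level. Of 2967 genes compared, 72 were at least 2-fold higher and 10 at least 2-fold lower at E16.5. Higher members outnumbered lower ones in the lists of LEC identity (7 of 12, median 0.62), valve (4 of 7, median 0.99), flow response (6 of 8, median 1.06), leukocyte traffic (5 of 6, median 1.05), MHC (3 of 5, median 0.99), interferon (4 of 4, median 0.94), matrix (5 of 14, median 0.53) and immediate-early genes (4 of 10, median 0.53). DNA replication genes were lower in 7 of 17 (median −0.53), G2 and mitosis genes in 2 of 16 (median −0.39) and fetal RNA-binding and let-7 target genes in 3 of 4 (median −1.11). Sex-linked genes were higher in 3 of 4 (median 0.80, percentile 99.45). Cells with Y-linked UMIs and none of Xist were 24.1% of LEC-like cells at E14.5 and 37.3% at E16.5.

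The later prenatal step was addressed by E18.5 against E16.5, with 679 and 526 cells. Lrg1 was 5.99-fold higher at E18.5 (5.03 to 7.17), Stmn2 4.99-fold (4.17 to 5.99) and Cldn11 4.01-fold (3.402 to 4.74). Of the epithelial transcripts, Lyz1 was at least 171-fold higher against the floor, with an exact lower limit of 138.7, and Ager 19.9-fold higher (12.5 to 34.0). Hpgd was 3.60-fold lower (2.91 to 4.48), Basp1 2.74-fold (2.26 to 3.34), Fbln1 2.24-fold (1.87 to 2.68), Dctpp1 1.91-fold (1.69 to 2.17) and the cyclin gene Ccnd2 1.90-fold lower (1.75 to 2.07). Of 2937 genes compared, 66 were at least 2-fold higher, 18 of them pseudogenes or numbered models, and 3 at least 2-fold lower. All 6 interferon response genes were higher (median 1.75), with Isg15 at 3.81 and 40.5 CPM and Ifitm3 at 246 and 725 CPM. Flow response genes were higher in 7 of 9 (median 0.96), valve genes in 4 of 8 (median 0.68), MHC genes in 4 of 7 (median 0.65), glucocorticoid response genes in 5 of 7 (median 0.90) and immediate-early genes in 8 of 12 (median 0.83). LEC identity genes were higher in 1 of 12 (median 0.38), and none of 14 matrix genes was 1.5-fold apart (median 0.14). DNA replication genes were lower in 12 of 16 (median −0.66) and G2 and mitosis genes in 10 of 16 (median −0.76). Sex-linked genes were lower in 1 of 4 (median −0.43, percentile 1.24).

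**Figure D3:**
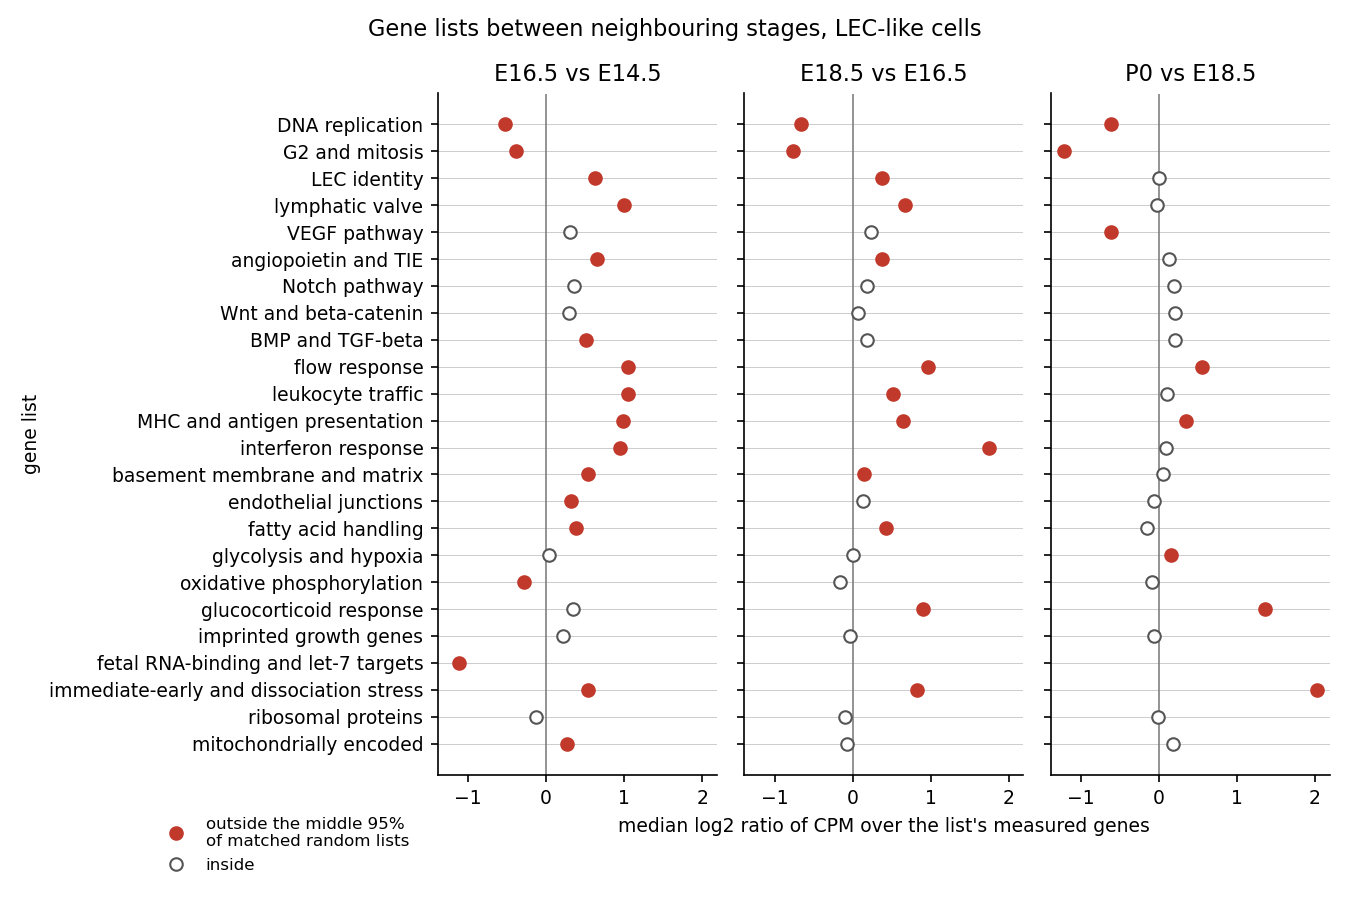
Median log2 ratio of CPM (horizontal axis) of each gene list but the sex-linked one (vertical axis) for the 3 comparisons of neighbouring stages in LEC-like cells, with filled points outside the middle 95% of matched random lists and open points inside. The fetal RNA-binding list has no point where fewer than 3 members were measured, and the immediate-early list had the highest median of P0 against E18.5, 2.03.

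How LEC-like cells differed across birth was asked of P0 against E18.5, with 1687 and 679 cells. Immediate-early genes, which respond within minutes to signals and to tissue dissociation, were higher at P0. Fos had 125 CPM at E18.5 and 1101 CPM at P0, an 8.79-fold higher level (8.23 to 9.40), Egr1 was 9.68-fold higher (8.48 to 11.1) and Fosb 9.17-fold (7.64 to 11.1). The matricellular protein gene Cyr61, also named Ccn1, was 13.4-fold higher (12.2 to 14.9), the flow response gene Klf4 6.86-fold (6.42 to 7.33) and the neuropeptide gene Nts 7.53-fold (7.04 to 8.06). Cell division genes were lower, with Top2a 2.32-fold lower (2.08 to 2.59).

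Of 2984 genes compared, 117 were at least 2-fold higher and 66 at least 2-fold lower at P0. Other high ratios belonged to Dusp5, a phosphatase of the ERK pathway, at 24.8-fold (15.8 to 41.4), the transcription factor gene Cebpb at 9.22-fold (8.44 to 10.1), the endothelial gene Apold1 at 9.02-fold (8.45 to 9.63), Rnf19b at 8.32-fold (6.45 to 10.9), thrombospondin, Thbs1, at 8.13-fold (7.31 to 9.07) and the cell cycle inhibitor gene Cdkn1a at 7.73-fold (6.54 to 9.19). Among the lowest ratios, the epithelial transcripts Lyz1 and Ager were 24.6-fold (18.03 to 34.3) and 8.04-fold lower at P0 (6.40 to 10.2). In blood endothelial clusters 13 and 14 Lyz1 was 35.3-fold and 44.1-fold lower, and Ager 12.1-fold and 13.2-fold lower. Lamtor3 was 14.2-fold lower (10.5 to 19.7), the noncoding RNA AY036118 10.3-fold (8.03 to 13.4) and Lars2 4.43-fold (3.73 to 5.29). In clusters 13 and 14 Lamtor3 was 22.8-fold and 14.9-fold lower, and AY036118 8.77-fold and 10.8-fold lower. Lars2 was 5.02-fold lower in cluster 13 and 4.40-fold lower in cluster 15. The lower levels of these genes were therefore not particular to LEC-like cells. The histone genes Hist1h2ap and Hist1h2ak were 7.78-fold (7.33 to 8.26) and 6.54-fold lower (5.88 to 7.30), and a copy of Ccl21b 4.25-fold lower (3.63 to 4.99). Clec2d, a ligand of a natural killer cell receptor, was 4.27-fold lower (3.55 to 5.15), Ccdc85b 3.19-fold (2.88 to 3.54), the glutathione transferase gene Gstp1 2.98-fold (2.75 to 3.23) and Wdr89 2.72-fold lower (2.55 to 2.91). Clec2d was also 3.47-fold, 6.68-fold and 4.43-fold lower in clusters 13, 14 and 15.

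All 12 immediate-early genes were higher at P0, with a median log2 ratio of 2.03, among them Dusp1 at 5.48-fold (5.08 to 5.92) and Junb at 4.24-fold (3.998 to 4.50). Glucocorticoid response genes were higher in 4 of 7 (median 1.37), with Sgk1 at 3.995-fold (3.74 to 4.28), and flow response genes in 4 of 9 (median 0.55), with Klf2 at 4.55-fold (4.35 to 4.76). All 15 genes of G2 and mitosis were lower (median −1.22), and so were 9 of 16 DNA replication genes (median −0.62). VEGF pathway genes were lower in 4 of 5 (median −0.61, percentile 2.18), with Nrp1 4.67-fold (3.02 to 7.42) and Kdr 1.53-fold lower (1.46 to 1.60). LEC identity genes went both ways, with 2 of 12 higher, 2 lower and a median of 0.01. Lyve1 was 1.76-fold higher (1.71 to 1.81) and Sox18 1.97-fold lower (1.85 to 2.10). Valve genes had 2 of 8 higher and 1 lower (median −0.02), with Nfatc1 2.93-fold higher (2.67 to 3.21) and Gja4 1.83-fold lower (1.73 to 1.95). Of the angiopoietin and TIE genes 2 of 5 were higher (median 0.13), among them Angpt2 at 2.58-fold (2.34 to 2.86).

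The interferon list, so much higher at E18.5 than at E14.5, had a median of 0.09 at P0 against E18.5 (1 of 6 higher), and the MHC list 0.35 (0 of 7 apart, percentile 98.3). Medians of the other lists were 0.19 for Notch (3 of 7 higher, 1 lower), 0.20 for Wnt (1 of 7 higher, 1 lower), 0.21 for BMP and TGF-beta (1 of 9 higher), 0.11 for leukocyte traffic (3 of 8 higher, 1 lower), 0.05 for matrix (1 of 14 higher, 1 lower), −0.06 for junctions (1 of 7 lower), −0.15 for fatty acid handling (2 of 12 higher, 3 lower), 0.16 for glycolysis and hypoxia (2 of 16 higher, 1 lower, percentile 97.7), −0.09 for oxidative phosphorylation (0 of 16 apart), −0.07 for imprinted growth genes (2 of 10 higher, 1 lower), −0.02 for ribosomal proteins and 0.18 for mitochondrially encoded genes. Within these lists Ccl2 was 6.23-fold higher (5.16 to 7.58), Cxcl12 5.00-fold lower (3.38 to 7.57) and Dlk1 30.3-fold lower (18.04 to 54.9). The sex-linked list had a median of −6.47, since the Y-linked gene Ddx3y had 20.5 CPM at E18.5 and 0 at P0, where 0 of 1687 LEC-like cells held a UMI of a Y-linked gene.

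Of the 66 lower genes, 30 were pseudogenes or numbered gene models, out of 49 compared, and without such genes the split was 114 higher and 36 lower. Median-of-ratios scaling moved all ratios of P0 against E18.5 by 0.14 on the log2 scale and gave 157 higher and 53 lower. With a 10 CPM filter, no CPM filter or all cells kept, the split turned, and more genes were lower than higher. Those counts are given with the dependence on the processing.

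P0 against E14.5, the ends of the series, was compared with 1687 and 585 cells, for the full span of stages. Of 3224 genes, 430 were at least 2-fold higher and 334 at least 2-fold lower at P0. Fgl2 had 23.8 CPM at E14.5 and 1437 CPM at P0, Lrg1 2.11 and 235 CPM, and Lyve1 120 and 1648 CPM. The flow response genes Klf4 and Klf2 had 17.1 and 873 CPM and 94.9 and 1302 CPM. Mdk had 113 CPM at E14.5 and 28.6 CPM at P0, Basp1 and Igf2bp1 were also lower at P0, and Ube2c had 448 and 90.8 CPM. Aqp1, with 14.6, 158, 411 and 213 CPM from E14.5 to P0, and Gja4, with 24.0, 124, 297 and 162 CPM, were highest at E18.5.

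The positions of the main genes on GRCm38 are as follows. Prox1 (ENSMUSG00000010175) lies on chromosome 1 from 190118035 to 190170714, Lyve1 (ENSMUSG00000030787) on chromosome 7 from 110850607 to 110863239, Foxc2 (ENSMUSG00000046714) on chromosome 8 from 121116171 to 121118895, Fgl2 (ENSMUSG00000039899) on chromosome 5 from 21372642 to 21378374, Lrg1 (ENSMUSG00000037095) on chromosome 17 from 56119678 to 56122001 and Mdk (ENSMUSG00000027239) on chromosome 2 from 91929805 to 91932297. Hmga2 (ENSMUSG00000056758) lies on chromosome 10 from 120361275 to 120476469, Fos (ENSMUSG00000021250) on chromosome 12 from 85473890 to 85477273, Klf4 (ENSMUSG00000003032) on chromosome 4 from 55527143 to 55532466 and Cyr61 (ENSMUSG00000028195) on chromosome 3 from 145646976 to 145649981. All are annotated as protein-coding genes.

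How many LEC-like cells were dividing at each stage was read from the genes of G2 and mitosis. At least 3 of the 16 genes had a UMI in 259 of 585 cells at E14.5 (44.3%, 40.2 to 48.4), 155 of 526 at E16.5 (29.5%, 25.6 to 33.6), 113 of 677 at E18.5 (16.7%, 13.96 to 19.7) and 130 of 1652 at P0 (7.87%, 6.62 to 9.27), with cells thinned to 3000 UMIs. The shares thus lay apart by more than their counting intervals, in the order of the stages. Without thinning they were 75.04%, 46.8%, 24.7% and 10.97%. Exactly 2 or 3 of the genes were seen in 134, 68, 44 and 55 cells, and 0, 0, 2 and 35 cells were too shallow to be thinned. In the epithelial-like cluster 11, 19 of 36, 6 of 22, 1 of 133 and 0 of 8 cells from E14.5 to P0 had at least 3 of the genes (52.8%, 27.3%, 0.752% and 0%), and in the unnamed cluster 6, led by S100a8, 10 of 24, 8 of 39, 12 of 77 and 3 of 14 (41.7%, 20.5%, 15.6% and 21.4%). Among all cells other than LEC-like ones the shares were 45.5%, 24.4%, 7.04% and 5.96%. Since the shares of these other cells were as high as that of LEC-like cells at E14.5, background from free RNA cannot be bounded at that stage. LEC-like clusters 0 and 8 held 585 of 585, 502 of 526 and 545 of 679 LEC-like cells at E14.5, E16.5 and E18.5, whereas cluster 1 held 1473 of 1687 at P0, and a cluster mostly of 1 library cannot be separated from that library.

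Whether valve-forming cells could be told from other LEC-like cells was asked by clustering these cells alone. A cluster with the valve genes Foxc2, Gata2, Gja4, Cldn11 and Nfatc1 held 0 of 585 cells at E14.5, which allows up to 0.513% as 3 counts of the total and up to 0.629% by the exact interval, 7 of 526 at E16.5 (1.33%, 0.537 to 2.72), 32 of 679 at E18.5 (4.71%, 3.25 to 6.59) and 114 of 1687 at P0 (6.76%, 5.61 to 8.06). At E18.5 Cldn11 was 19.6-fold (17.1 to 22.5), Gata2 6.50-fold (4.76 to 8.76) and Foxc2 4.57-fold higher (3.31 to 6.21) in the cluster than in the other LEC-like cells, and at P0 the ratios were 12.1, 3.76 and 2.91. The valve markers Gja1, Itga9 and Clu were not higher, and Lyve1 was lower, with 240 CPM inside and 966 CPM outside the cluster at E18.5. Its leading genes were Fxyd2, the connexin gene Gjd3, Neo1, Sbspon and the BMP family gene Gdf10, between 42.3-fold and 101-fold higher at E18.5. A second cluster, with 14, 59, 147 and 690 cells from E14.5 to P0, shared 5, 5, 4 and 1 of the valve markers and was left unnamed, and no capillary cluster could be named. With each library clustered alone, the valve share was 12.5% at E16.5, 18.7% at E18.5 and 10.4% at P0, outside the intervals above. Because the boundary of the valve cluster moved with the clustering, its shares are given as values without an order.

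**Figure D4:**
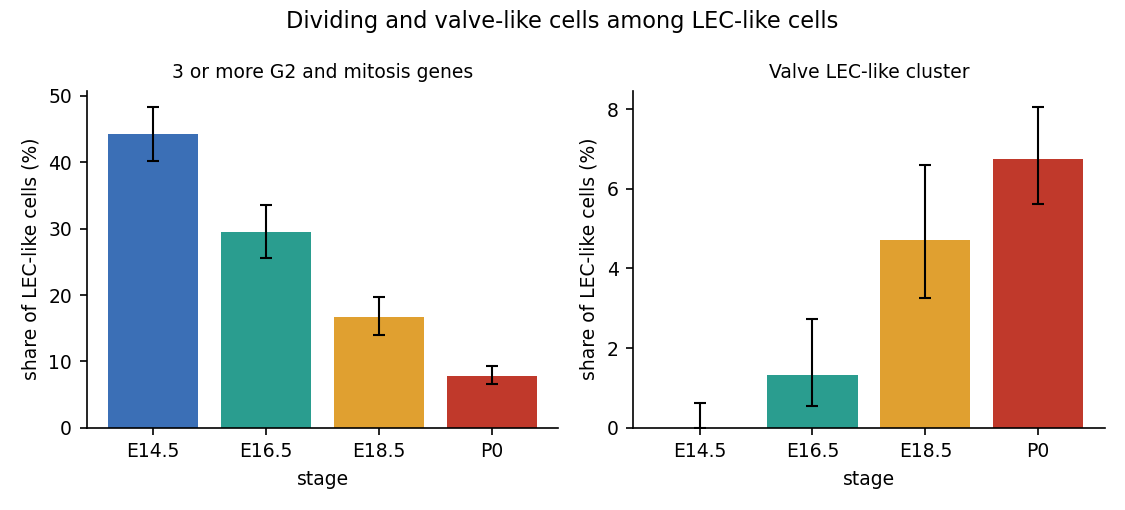
Share of LEC-like cells (%, vertical axes) with at least 3 genes of G2 and mitosis after thinning, left, and in the valve cluster, right, at the 4 stages (horizontal axes), with exact binomial 95% intervals as error bars. The dividing share was 44.3% at E14.5 and 7.87% at P0.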

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

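The tests of a difference between the E18.5 and P0 libraries that cell types share were written before their results were seen, and all other tests in this part were chosen afterwards. Although the sort selected CD45-negative, CD31-positive and GFP-positive cells, cells of 3 other named classes were present. Mesenchymal-like cells, with Col1a1 and Mfap4 among their leading genes, made up 11.4% of the E14.5 library. Myeloid-like cells, with C1qa, were 5.02% of the E16.5 library. Epithelial-like cells, with Sftpc, were 6.07% of the E18.5 library. Unnamed clusters held further kinds of cells. Cluster 6, led by S100a8, was 3.51% of the E18.5 library, and cluster 12, led by Mcpt8, was 1.38% of the E16.5 library.

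Epithelial marker UMIs were also present inside LEC-like cells of E18.5, where 99.6% of cells held a Sftpc UMI, which argues against a few doublets as their source. Free RNA from the epithelial cells remains a possible explanation, since Sftpc had 721 CPM in LEC-like cells and 728, 761 and 714 CPM in clusters 10, 13 and 14, and over 4 epithelial markers the median log2 ratio of LEC-like cells to the cluster farthest from them was −0.11. The epithelial-like cluster itself had 87642 CPM of Sftpc. No biological explanation was tested for this pattern.

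The 117 genes at least 2-fold higher at P0 than at E18.5 had a median log2 ratio of 1.39 in LEC-like cells, and 1.41 in cells with Xist UMIs alone, which argues against the sex of the cells as the cause, although the P0 library held almost no Y-linked UMIs, 2 in 3215 cells. The lower depth of P0 stays open, since thinning leaves expected CPM as they were and the 1.47 it gave decides nothing. In blood endothelial clusters 13, 14 and 15 the 98, 103 and 92 of these genes that were measured had medians of 0.81, 0.89 and 0.66, which are 0.58, 0.63 and 0.47 of the medians of the same genes in LEC-like cells. The genes were chosen by their ratio in LEC-like cells of the same libraries, which tends to pull these shares down. A difference between the libraries that cell types share may therefore account for part of the set and cannot be told apart from birth, because each stage is 1 library and these shares lie on both sides of the 0.5 fixed beforehand. For the immediate-early and dissociation list, with 2.03 in LEC-like cells, a shift of 1 size in all endothelial cells is argued against by medians of 0.57, −0.09 and 0.55. Arterial cluster 7 had 1.76. It also had 1.46 for LEC identity genes and so may hold LEC-like cells or their RNA. Such cells or RNA, at the mean LEC-like level, would not lift a gene above that level. Yet Egr1 of this list had 399 CPM in cluster 7 and 299 CPM in LEC-like cells at P0. Other members were not compared in this way, and how much of the 1.76 belongs to arterial cells was not tested. Both birth and the response of cells to dissociation stay open and untested.

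The 66 genes at least 2-fold lower at P0 had a median of −2.18 in LEC-like cells, and the 58, 60 and 57 measured in blood endothelial clusters 13, 14 and 15 had −2.22, −2.41 and −2.56, so that a difference between the libraries that cell types share may account for this set. In LEC-like cells with few cell cycle genes, 59 of the genes, those at 10 CPM or more there, had a median of −2.28. These genes were thus lower at P0 in such cells too. The value cannot weigh fewer dividing cells for the 66, because the 10 CPM filter leaves out genes seen mainly in dividing cells. Only 1 of the 59 was in the cell cycle lists. The size also did not stay for each gene, since Hist1h2ap had −2.96 in all LEC-like cells and −1.16 there, and 2810417H13Rik −1.09 and −0.72. The other 7, among them Cenpf, Cdk1 and Top2a, had few UMIs and a median of −1.13, and for them fewer dividing cells stay open. Pseudogenes and numbered gene models were 30 of the 66, with a median of −3.28 in LEC-like cells. In clusters 13, 14 and 15 their medians were −3.21, −3.29 and −2.94, and in each cluster all 29 measured were at least 2-fold lower. The gene list of P0 also has a column that the others lack. Another way of counting in P0 alone is still left open rather than favoured, because 40.5% of such genes were at least 2-fold lower and 24.3% higher at P0 than at E14.5. In addition, 33 of 45 were higher at E18.5 than at E14.5 and 18 of 45 higher than at E16.5, where P0 has no part. The other 36 genes had a median of −1.34 in LEC-like cells, and the 29, 31 and 28 measured in the 3 clusters −1.06, −1.59 and −1.37. A biological difference between the stages that acts on all endothelial cells stays open and was not tested.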

How the results depend on the processing

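The LEC-like clusters left out or chosen anew, and the genes without pseudogenes and numbered models, were alternatives chosen after the data had been seen; the other alternatives were planned. No ratio of a named gene changed sign under any alternative, whereas some list medians near 0 did. There were 372 genes at least 2-fold apart, E18.5 vs E14.5, and a 10 CPM filter gave 1077, no CPM filter 2794 and all cells kept 840. For genes at least 2-fold apart, E16.5 vs E14.5, the 82 became 299, 1374 and 206 in the same order, and for genes at least 2-fold apart, E18.5 vs E16.5, the 69 became 271, 1218 and 201. For genes at least 2-fold apart, P0 vs E18.5, the CPM filters gave 507 and 2055 in place of 183. The split of 117 higher and 66 lower there became 241 and 266, 562 and 1493, and with all cells kept 91 and 136; the cause was not tested. For genes at least 2-fold apart, P0 vs E14.5, the CPM filters gave 1937 and 3838 in place of 764. Lower filters let in genes with few counts, and the mix of all cells differs between libraries. With at least 1000 genes and at most 5% mitochondrial UMIs per cell, LEC-like cells were 16.9% at E16.5, 28.3% at E18.5 and 50.4% at P0; the cause was not tested. The dividing share from E14.5 to P0 was 59.1%, 38.0%, 20.2% and 9.81% with at least 2 genes, 29.1%, 22.4%, 11.4% and 5.63% with at least 5 genes, and 75.04%, 46.8%, 24.7% and 10.97% at full depth, as the thresholds and depth set. The valve share was 6.63% at E18.5 and 11.1% at P0 at a Leiden resolution of 1.0, and 12.5% at E16.5, 18.7% at E18.5 and 10.4% at P0 with each library clustered alone, where the order of E18.5 and P0 turned; the cause was not tested. The other 80 values for these results stayed within their limits. Of the list medians, 870 stayed and 47 moved, and of the ratios of named genes 534 stayed and 122 moved beyond their counting intervals. Between 64 and 68 of the 68 named ratios were at least 2-fold under each alternative that could use all of them; Dctpp1 and Ccnd2 were below 2-fold in the report. Cells with Y-linked UMIs alone gave no values for P0, which had 0 such cells, and 43 of the 44 other ratios were at least 2-fold. Fetal RNA-binding genes had fewer than 3 measured members in E18.5 against E16.5 and P0 against E18.5. The valve share at E16.5 rests on 7 cells.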

Other observations

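The tests described in this part used lists fixed beforehand, but the choice of clusters was made after the result for LEC-like cells had been seen. Blood endothelial clusters 13, 14 and 15 had enough cells at both E18.5 and P0 to be compared. The BMP target gene Id1 was 4.88-fold (95% interval 4.25 to 5.62), 8.91-fold (8.07 to 9.87) and 6.34-fold (4.81 to 8.48) higher at P0 in these clusters, and 1.61-fold higher (1.49 to 1.75) in LEC-like cells. Smad6, an inhibitor of BMP signalling, was 4.91-fold (3.89 to 6.27) and 6.26-fold (5.27 to 7.496) higher in clusters 13 and 14. Sgk1 was 5.77-fold (5.00 to 6.68) higher in cluster 13 and 3.96-fold (3.19 to 4.94) in cluster 15, and the glucocorticoid response list had medians of 1.05, 1.51 and 0.57. Interferon response genes had medians of −0.43, −0.58 and −0.48 in the 3 clusters and 0.09 in LEC-like cells. Cluster 14 also had Nrarp, a Notch target, 17.0-fold higher at P0 (12.02 to 24.7), and Fos 0.519 times the E18.5 level (0.4998 to 0.539). Whether these clusters differ from LEC-like cells was not tested.

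Arterial-like cluster 7, with 43, 120, 106 and 56 cells from E14.5 to P0, was the only blood endothelial cluster outside clusters 2 and 4 with more than 20 cells at E14.5. At E18.5 against E14.5 its fatty acid binding protein gene Fabp4 was 40.4-fold higher (17.2 to 125) and Cytl1 46.1-fold higher (19.6 to 143). The collagen genes Col4a1 and Col4a2 were 7.85-fold (6.25 to 9.95) and 11.2-fold lower (8.04 to 15.9), whereas Col4a1 was 2.05-fold higher in LEC-like cells. Mdk was 7.75-fold lower (6.01 to 10.1) and Nnat 24.7-fold lower (9.98 to 78.9). The list medians were −1.21 for fetal RNA-binding and let-7 target genes, 1.31 for interferon response, 1.46 for MHC, −0.83 for G2 and mitosis, −0.19 for matrix and 0.21 for fatty acid handling, where LEC-like cells had −2.50, 3.25, 2.20, −1.02, 0.62 and 1.08. Medians were 1.09 for LEC identity, 1.86 for immediate-early, 1.64 for glucocorticoid response and 0.99 for angiopoietin and TIE genes, where LEC-like cells had 1.01, 1.63, 1.77 and 1.02, and flow response genes had 0.89 against 1.75. DNA replication genes had −0.17, leukocyte traffic genes 0.36, valve genes 0.62, VEGF pathway genes 0.07, imprinted growth genes −0.47 and mitochondrially encoded genes −0.58, where LEC-like cells had −1.22, 1.57, 1.45, 0.70, 0.34 and 0.15. At P0 against E18.5 the cluster had 1.46 for LEC identity genes (9 of 11 higher) and 1.40 for valve genes, and Nts had 1.72 and 271 CPM.

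At a Leiden resolution of 1.0, 38 cells of the 4 libraries formed a cluster with 5 of 6 cardiac muscle markers, among them Myl7 and Actc1, with 0, 6, 14 and 18 cells from E14.5 to P0. Cells with a UMI of a Y-linked gene and none of Xist were 24.1%, 37.3% and 22.5% of LEC-like cells at E14.5, E16.5 and E18.5, and 0 of 1687 at P0, where 98.9% held Xist UMIs alone.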
